A study of Mus musculus with 2 samples.

How the data were processed

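Gene expression was measured in 2 libraries of sorted mouse regulatory T (Treg) cells, 1 labelled Nr4a-deficient and 1 labelled wild-type, from mice 5 weeks old. Per the labels' protocols, the sorted cells were lysed directly, total RNA was purified on columns, and cRNA labelled with the dye Cy3 was prepared with a low-input amplification kit. Amplification from little RNA can distort the levels of rare transcripts. Each library was hybridised to 1 single-colour Agilent array. Both arrays were on 1 slide and came from 1 scan, so slide and scan did not differ between the groups. The surface markers used in the sort, the tissue, the mouse strain and the number of animals behind each library were not given in the sources used here.

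The deposited scanner files hold intensity values per spot on a linear scale. Per the file headers, they were made with Agilent Feature Extraction 10.7.3.1, which subtracted background and removed spatial and multiplicative trends within each array. Nothing in the headers records a normalization between arrays. The authors' deposited value table also holds intensity values. Set against the scanner files, it held the processed signal of the same array on a linear scale, not centred, with repeated spots averaged. Of its 39485 probes, 99.6% in the library labelled Nr4a-deficient and 99.5% in the wild-type library lay within 1% of the scanner value. Its column medians were 143.7 and 156.8, respectively. It was used as an alternative source.

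Each array had 44397 spots, of which 43020 were gene spots for 39348 probes. Of these probes, 399 were printed in 10 spots. Spots flagged as outliers by the scanner software were left out, 173 in the library labelled Nr4a-deficient and 209 in the wild-type library. No spot was saturated on either array. The processed signal was put on the log2 scale, and the 75th percentile of all gene probes of the array was subtracted. That percentile was 1762 in the library labelled Nr4a-deficient and 2047 in the wild-type library. Repeated spots were averaged. A probe counted as well above background when over 50% of its spots carried that call of the scanner software. This held for 23113 probes (58.7%) in the library labelled Nr4a-deficient and 21872 (55.6%) in the wild-type library. The lowest signal with that call was 51.1 and 73.8, respectively, so a dim transcript had to be brighter to be called on the wild-type array. The background itself was also higher there, with a median of 12.9 and 17.9 over 153 negative-control spots.

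A gene was represented by its brightest probe among those well above background on at least 1 array. This rule can pick a bright probe that differs from the gene's other probes. A gene well above background on 1 array only has a bound. The brighter array's value was set against the higher of the dim probe's own value and the lowest scaled value of probes well above background on that array, and the result is given as "at least". No fold was given for genes not well above background on either array. Gene names were updated through RefSeq's gene table of assembly GRCm38.p6, by accession for 27184 probes, by symbol for 3566 and by synonym for 562. The other 8036 probes kept the name of the array design, which gave 30069 gene names in all. Probe coordinates are those of the array design, on genome build mm9. No mm9 annotation was used here, so the exon or untranslated region under a probe is not given.

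Each group had 1 library, so there was no test between genotypes, and no p-value is given. The number of arrays limits the precision. The spread of spots of 1 probe within an array describes spot noise only and leaves out differences between animals, sorts and RNA preparations. A change of at least 2-fold was counted as higher or lower. For each of 27 gene lists, the median log2 difference (library labelled Nr4a-deficient minus wild-type) of the detected genes was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart when its median lay outside the central 95% of these random lists. This describes these 2 libraries and is not a test of genotype. Lists with under 5 detected genes got no rank. A list of plasmacytoid dendritic cell markers was added after the data were seen.

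The design, the lists, the counts and the rule for named genes were fixed before the data were examined. The rule named the 3 Nr4a genes, a panel of 16 T cell genes, and the 10 genes with the highest and the 10 with the lowest difference among those well above background on both arrays. For these 20, all probes above background on both arrays had to point the same way, and predicted or clone names were left out. It also named the 4 highest bounds in each direction and up to 2 members at each end of every list that passed 2-fold. Some genes that the rule names are not reported here. Genes named outside this rule are identified as chosen after their values were seen.

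Alternatives covered the scale of the arrays (median of all probes, 75th percentile of probes well above background on both arrays, and spike-in control RNAs), cyclic loess, and background correction with normexp (offset 50) followed by quantile normalization. They also covered the deposited value table, the filter on dim probes, the mean over a gene's probes, the flagged spots, the fold threshold, the mean of a list, lists without their most changed member, and 10 expression bins. Leaving out genes of the other-cell marker lists, and setting genes with a bound to that bound, were added after the data were seen. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.

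The counting was tested on simulated data for this comparison with 16320 genes, of which 200 were changed and all carried spot noise. At a simulated 1.5-fold change 5 of the 200 (2.5%) passed the 2-fold threshold, at 2.5-fold 190 (95%) and at 4-fold all 200. Of the unchanged genes 5, 3 and 3 passed, respectively. The ranking of lists was tested on 14582 genes with unchanged and shifted lists of 20 genes. Of 200 unchanged lists, 5 (2.5%) stood apart, and of 200 lists shifted by 0.5 on the log2 scale all did. Smaller shifts were not simulated. The random lists were matched on expression only, so this rate need not hold for lists of genes that vary together. Of the 25 lists ranked in the data, 12 lay above and 6 below the central 95%, so standing apart was common here.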

Results

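Treg cells are CD4 T cells that restrain immune responses, and the Nr4a genes (Nr4a1, Nr4a2 and Nr4a3) encode nuclear receptors induced by T cell receptor signals. Total RNA of sorted Treg cells was profiled on 1 array per genotype, with 1 library labelled Nr4a-deficient and 1 labelled wild-type. The comparison asks which transcripts of Treg cells depend on the Nr4a receptors, with genes of T helper 2 (Th2) and follicular helper T (Tfh) cells of particular interest. The arrays had no replicates, so no difference was tested between genotypes, and each value below describes these 2 libraries. Differences are given on the log2 scale as the library labelled Nr4a-deficient minus wild-type, after each array was scaled to its 75th percentile. Between spots of 1 probe on 1 array, the SD of a difference was 0.074 for bright probes (over 1 on the scaled log2 axis) and 0.32 for dim ones (under -3). Of 20206 such spot pairs, 30 (0.148%) differed at least 2-fold. The 8 spike-in RNAs above background on both arrays lay 0.36 ± 0.057 higher (SD, n = 8) in the library labelled Nr4a-deficient after scaling. With the spike-ins as the scale, every log2 difference is therefore 0.36 lower, and differences between 0 and 0.36 change sign.

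The probes for the targeted genes went against the label in 2 of 3 cases. Nr4a1 was 1.82-fold higher in the library labelled Nr4a-deficient (log2 difference 0.86), and Nr4a2 was 1.97-fold higher (0.98, with 0.68 at its other probe). Across the alternative scalings, the lowest value was 0.50 for Nr4a1 and 0.61 for Nr4a2. The probe of Nr4a3 was not well above background on either array, so no fold is given. Its 10 spots averaged 23.7 ± 8.9 (SD) intensity units in the library labelled Nr4a-deficient and 72.0 ± 7.3 (SD) in the wild-type library, with no overlap between the spots of the arrays. On mm9, the Nr4a1 probe lies on chromosome 15 from 101105071 to 101105130, the Nr4a2 probes lie on chromosome 2 from 56960699 to 56960758 and from 56959637 to 56959696, and the Nr4a3 probe lies on chromosome 4 from 48080690 to 48083876. The labels do not say which part of each gene was deleted, and a probe outside that part checks nothing. For this reason the text writes "the library labelled Nr4a-deficient", and each direction rests on that label.

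Across the 16320 genes well above background on both arrays, 433 were at least 2-fold higher and 509 at least 2-fold lower in the library labelled Nr4a-deficient, together 5.77%. The remaining 94.2% lay within 2-fold, and the values of the 2 arrays correlated with r = 0.981 across genes, which are not independent replicates. A further 1588 genes were well above background only in the library labelled Nr4a-deficient, 438 of them with a bound of at least 2-fold, and 632 only in the wild-type library, 407 of them with such a bound. Measured values and bounds together gave 871 genes higher and 916 lower. With the measured values of dim probes in place of bounds, 1429 of 18540 genes were higher and 1064 lower, so 57.3% of the changed genes were higher. That split turned to 1089 higher and 1553 lower (41.2% higher) with the spike-ins as the scale, and to 432 higher and 499 lower (46.4% higher) when both arrays had to be above background. Of 124 changed genes with several probes above background on both arrays, 104 had all of these probes pointing the same way (83.9%), and 67 had all of them past 2-fold (54.0%).

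**Figure D1:**
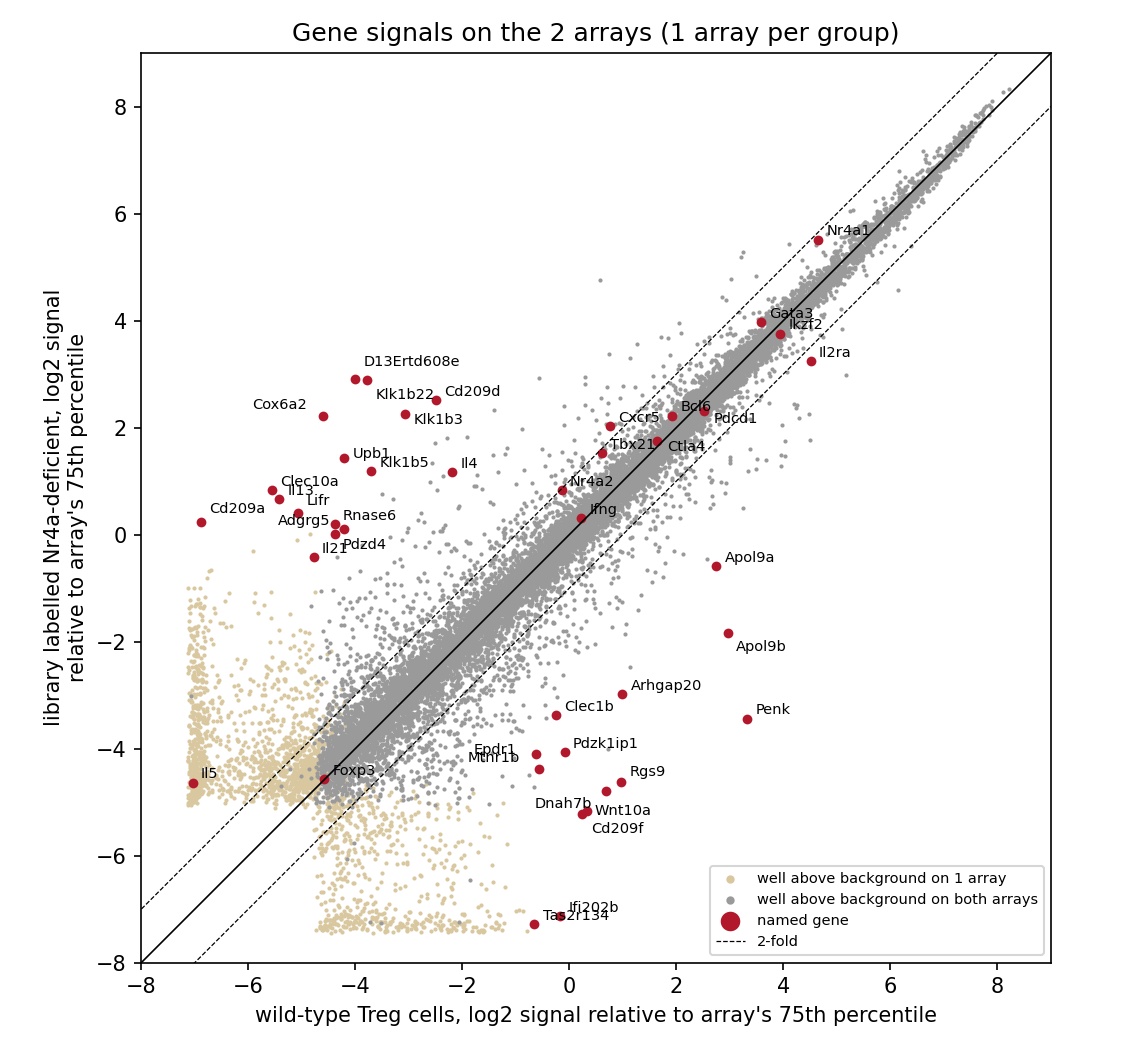
Scaled log2 signal of each gene on the wild-type array (x axis) and on the array of the library labelled Nr4a-deficient (y axis), 1 array per group, with dashed lines at 2-fold and named genes in red. Penk lies far below the diagonal (log2 difference -6.76) and Cox6a2 far above it (6.83), while 94.2% of the 16320 genes measured on both arrays lie between the dashed lines.

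Some cytokine genes of the Th2 and Tfh lists, Il4, Il13, Il10 and Il21, were higher in the library labelled Nr4a-deficient, and others were not. Il4, the defining Th2 cytokine, was 10.3-fold higher, and the SD of its 10 and 9 spots was 0.050 and 0.087 on the log2 scale. Il13, a second Th2 cytokine, was at least 43.8-fold higher, and Il21, the cytokine of Tfh cells, at least 20.5-fold higher. Il5 was above background only in the library labelled Nr4a-deficient, with a bound of 1.11-fold, Il3 lay at 0.038, less than the spike-in shift of 0.36, and Il24 was 2.07-fold lower. Il3 and Il24 were chosen after their values were seen. The transcription factor genes of these lineages differed less. Gata3 of Th2 cells lay at 0.38 and Bcl6 of Tfh cells at 0.30, or 0.020 and -0.063 with the spike-ins as the scale. Cxcr5, the receptor that guides Tfh cells into B cell follicles, was 2.41-fold higher, and its value was 0.90 on the spike-in scale, just under 2-fold. Markers of B cells were also higher in that library, with a median of 1.07. Whether RNA of B cells added to the Cxcr5 signal was not tested.

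The Th2 list did not move as a block. Of its 18 detected genes, 4 were at least 2-fold higher, 4 at least 2-fold lower and 10 within 2-fold or with a smaller bound. Il10 was 7.16-fold higher, as was Areg (5.12-fold), which encodes amphiregulin and was chosen after its value was seen, whereas Ccr8 was 2.62-fold and Ccr4 2.26-fold lower and Il17rb lay at -1.63. The list's median was 0.24, above 9987 of 10000 matched random lists, and -0.12 with the spike-ins as the scale. Its place outside the central 95% ended at percentile 91.0 without Il13, at 87.1 when both arrays had to be above background, at 92.6 without a filter on dim probes, and at 97.0 with genes at their bounds. The Tfh list moved in one direction past 2-fold, with 6 of 24 genes higher and none lower. Sostdc1, a secreted antagonist of Wnt and BMP signals, was at least 22.4-fold higher. The Tfh median was 0.22, above all 10000 matched lists, and -0.14 with the spike-ins as the scale. Markers of B cells, with a median of 1.07, were higher in the same library.

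The Treg signature was lower as a list, but its members went both ways. Of 33 detected genes, 22 lay below 0 and 11 above, with 4 at least 2-fold lower and 4 at least 2-fold higher. The median was -0.31, below all 10000 matched lists. Penk, which encodes proenkephalin, was 108-fold lower, Ikzf4, the gene of the Foxp3 partner Eos, 6.39-fold lower (log2 differences from -2.76 to -1.30 over its 3 probes) and Il2ra, the IL-2 receptor alpha chain, 2.42-fold lower. Gzmb (granzyme B) was 18.3-fold higher and Il10, an inhibitory cytokine, was 7.16-fold higher. Foxp3, the lineage factor, lay at 0.02, or -0.35 with the spike-ins as the scale, but its probe was close to background on both arrays, where the SD of a spot difference was 0.32. Ikzf2 lay at -0.18. Ctla4 lay at 0.11, or -0.26 with the spike-ins as the scale. Genes induced by IL-2 and STAT5 had a median of -0.29, above 1 of 10000 matched lists, with 3 of 16 at least 2-fold lower and none higher. Il2ra, Foxp3 and other members of this list also stood in the Treg signature, so the results of these lists are not independent. Lta, a cytokine of the tumour necrosis factor family, was 2.82-fold lower. By its mean in place of its median, the IL-2 and STAT5 list lay at percentile 2.68, inside the central 95%. Proliferation genes were lower by small amounts, with 37 of 41 below 0, a median of -0.32 below all 10000 matched lists, and none past 2-fold by measured value on both arrays or by bound. Erythroid and platelet markers were lower in the same library, with a median of -1.65, and markers of B cells (median 1.07) and of NK and CD8 T cells (median 0.42) were higher.

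Most genes of the Th1, Th17 and effector lists lay within 2-fold or had a smaller bound. In the Th1 list 5 of 21 genes were higher and 2 lower, with a median of 0.21, above 9994 of 10000 matched lists, and -0.16 with the spike-ins as the scale. The chemokine gene Ccl3 was 8.59-fold higher, and Xcl1 was at least 3.55-fold and Il18r1 2.03-fold lower. Tbx21, the Th1 lineage factor, lay at 0.92, and Ifng at 0.099, or -0.27 with the spike-ins as the scale. In the Th17 list, 2 of 13 genes were higher and 1 lower, with a median of 0.53, above 9999 matched lists. That median was the value of a gene below background in the wild-type library, and it was 0.18 with genes at their bounds (less than the spike-in shift of 0.36) and 0.21 with genes above background on both arrays. By its mean the Th17 list lay at percentile 87.4. The leukotriene receptor gene Ltb4r1 was 6.32-fold higher and Ccr6 was 6.70-fold lower. Il17a was not well above background on either array, and Il17f had a bound of 1.13-fold. The effector Treg and activation list had 7 of 31 genes higher and 2 lower, with a median of 0.23, above all 10000 matched lists, and -0.14 with the spike-ins as the scale. Klrg1, a receptor of terminally differentiated effector cells, was 2.75-fold higher. Natural killer (NK) and CD8 T cell markers were higher in the same library, with a median of 0.42, and 3 of the Th1 genes (Eomes, Gzmk and Nkg7) also stood in that marker list.

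The early genes induced by the T cell receptor had 4 of 30 higher and 1 lower, with a median of 0.14, above 9994 of 10000 matched lists, and -0.23 with the spike-ins as the scale. Ier3 was 15.2-fold higher, Fosl2, of the AP-1 family, 3.77-fold higher, and Cd83 2.35-fold lower. Naive or resting T cell genes had 4 of 23 higher and 1 lower, with a median of 0.081, above 9835 matched lists, and -0.28 with the spike-ins as the scale. Among them, Dapl1 was 4.39-fold higher and Sox4 3.37-fold lower, and 5 of the list's genes also stood in the other-cell marker lists. Chemokine and homing receptors split, with 7 of 27 higher and 4 lower. Cxcr6 was 3.74-fold higher, while Ccr10 was 7.49-fold and Ccr6 6.70-fold lower. Their median was 0.12, above 9978 matched lists, and -0.24 with the spike-ins as the scale. By its mean this list lay at percentile 94.6. Markers of B cells (median 1.07) and of NK and CD8 T cells (median 0.42) were higher in the same library.

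Interferon-induced genes had a median of -0.12, above 165 of 10000 matched lists, although Oasl2 was 6.83-fold and Ly6a 2.52-fold higher and none of the 36 was 2-fold lower. That place ended with cyclic loess (percentile 3.06), with normexp and quantile normalization (2.68) and with the mean over a gene's probes (4.35), and by the mean of the list the shift turned to 0.022. Co-inhibitory receptors (median -0.087, percentile 19.9), apoptosis genes (-0.11, 5.69), glycolysis genes (-0.039, 38.2), heat shock and stress genes (-0.065, 24.2), pan T cell genes (-0.079, 12.2) and housekeeping genes (-0.005, 55.9) lay inside the central 95% of their matched lists. The call of apoptosis genes depended on the processing and that of heat shock and pan T cell genes on the use of the median. Single members still differed. Lag3, a co-inhibitory receptor, was 3.23-fold higher, Cd96 4.40-fold and Trat1 2.65-fold lower, and Hmox1, which degrades haem, was 3.89-fold and Hspb1 3.61-fold lower. In the same library, erythroid and platelet markers were lower (median -1.65) and B cell markers higher (median 1.07). Cdkn1a, a cell cycle inhibitor, was 3.31-fold higher at its brightest probe, but its log2 difference turned to -1.02 with the mean of its probes. The 3 sex-linked genes detected were at 0.07 to 0.23, all well above background on both arrays, and their median of 0.15 became -0.22 with the spike-ins as the scale.

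**Figure D2:**
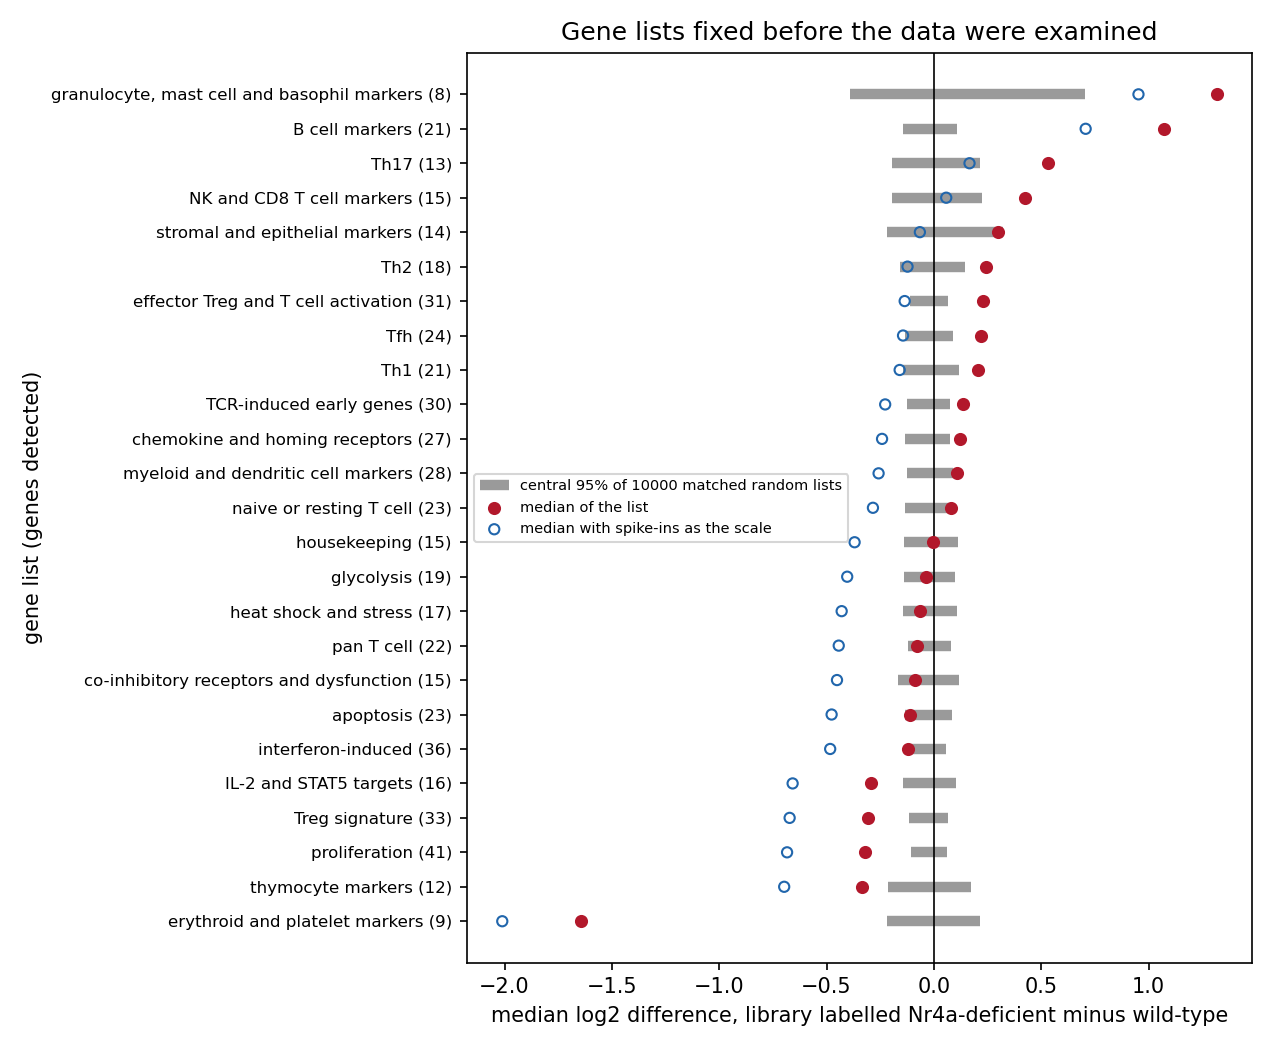
Median log2 difference (x axis, library labelled Nr4a-deficient minus wild-type) of each gene list with at least 5 detected genes (y axis, number detected in brackets), in red, over the central 95% of 10000 matched random lists in grey. Open circles give the same medians with the spike-ins as the scale, which lowers the lists and the random lists alike by 0.36 and turns 9 of the positive medians below 0, Th2 (0.24 to -0.12) and Tfh (0.22 to -0.14) among them.

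Markers of other cell types also differed between the 2 sorted populations, in both directions. B cell markers had 11 of 21 genes at least 2-fold higher and none lower, with a median of 1.07, above all 10000 matched lists. Fcrla was 7.67-fold and Spib, a transcription factor of B cells and plasmacytoid dendritic cells, 5.67-fold higher. NK and CD8 T cell markers had 5 of 15 higher and 1 lower (median 0.42, above 9995 matched lists), with the NK receptor genes Klrd1 at least 13.1-fold higher and Klrk1 higher by a log2 bound of 3.32, and Ctsw 2.90-fold lower. The other 9 lay within 2-fold. Among these, chosen after their values were seen, were Gzma (-0.16), Gzmm (-0.19), Gzmk (0.081), Prf1 (0.046) and Eomes (-0.38). In the whole list 11 genes lay above 0 and 4 below. The myeloid and dendritic cell list split into 6 of 28 higher and 5 lower. Its dendritic cell genes Itgax (6.27-fold) and Clec9a (5.63-fold) were higher, and its complement genes C1qc (3.03-fold) and C1qa (2.92-fold), made by macrophages, were lower. The median of that list was 0.11, above 9893 matched lists, and -0.26 with the spike-ins as the scale, and its place ended with cyclic loess (percentile 83.6), with the mean of a gene's probes (82.7) and by its mean (86.6). Of 9 erythroid and platelet markers, 8 were lower, with a median of -1.65, below all 10000 matched lists. The haemoglobin probes Hbb-bs (4.10-fold lower) and Hbb-b2 (3.85-fold lower) are near-identical genes that a probe may not tell apart.

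Fewer genes stood behind the remaining marker lists. Thymocyte markers had a median of -0.33, above 28 of 10000 matched lists. Rag1, of antigen receptor recombination, was at least 14.0-fold lower and Ccr9 2.35-fold higher. Without Rag1 this list lay at percentile 22.5, and with genes above background on both arrays its shift turned to 0.19 (percentile 98.1). Granulocyte, mast cell and basophil markers had 8 of 19 genes detected and a median of 1.32, above 9972 matched lists, with Mmp9 at least 3.21-fold and Siglecf at least 2.57-fold higher and Hdc, chosen after its value was seen, 4.90-fold higher. That place ended when both arrays had to be above background (percentile 31.2) and without a filter on dim probes (percentile 65.9), and the median was 0.70 with genes at their bounds. Stromal and epithelial markers had a median of 0.30 at percentile 96.5, or -0.066 with the spike-ins as the scale, with Cdh5 at least 8.10-fold and Cdh1 at least 4.70-fold higher. Without a filter on dim probes it lay at percentile 98.9.

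**Figure D3:**
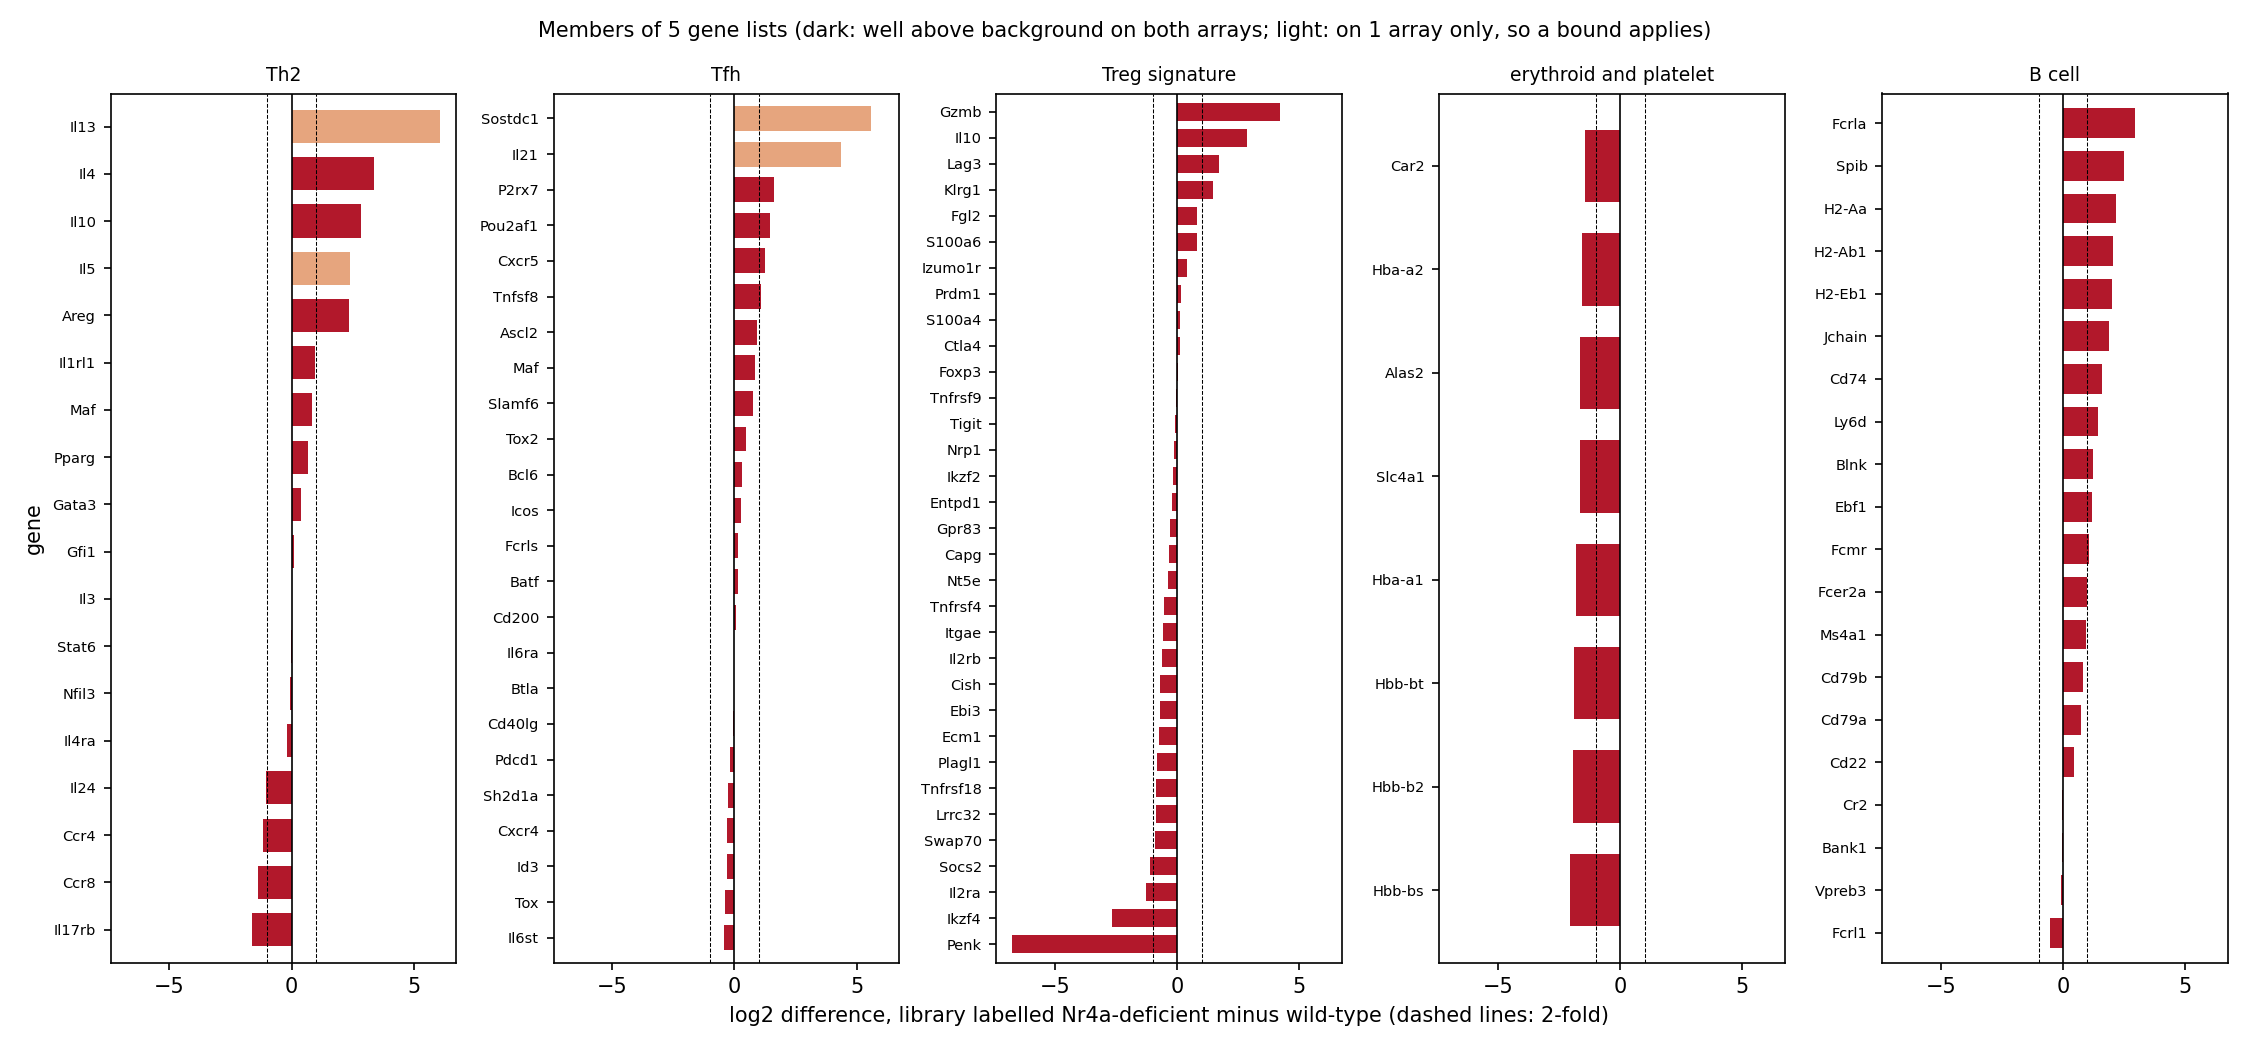
Log2 difference (x axis, library labelled Nr4a-deficient minus wild-type) of the detected members (y axis) of 5 gene lists, except those not reported here, with dark bars for genes well above background on both arrays and light bars for genes above it on 1 array. Il4 (3.36) and Il10 (2.84) stand against Il17rb (-1.63) in the Th2 list, and 8 of 9 erythroid and platelet markers lie below 0, as they do with the spike-ins as the scale, which lowers every bar by 0.36 and turns bars between 0 and 0.36 below 0.

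The genes with the highest differences among those measured on both arrays were D13Ertd608e (121-fold), Cox6a2 (114-fold), Klk1b22 (102-fold), Upb1 (49.9-fold), Klk1b3 (40.3-fold), Cd209d (32.1-fold), Klk1b5 (29.8-fold), Rnase6 (24.1-fold), Pdzd4 (21.0-fold) and Adgrg5 (19.9-fold). Of these, Cox6a2, Upb1, Cd209d and Rnase6 stood in the list of plasmacytoid dendritic cell markers that was added after the data were seen. Among genes with a bound, Clec10a was at least 49.2-fold, Lifr at least 36.5-fold and Cd209a at least 32.8-fold higher. Clec10a and Cd209a encode lectins of dendritic cells and macrophages. The lowest besides Penk were Rgs9 (48.5-fold), Dnah7b (44.5-fold), Apol9b (27.6-fold), Pdzk1ip1 (15.7-fold), Arhgap20 (15.6-fold), Mtnr1b (13.9-fold), Epdr1 (11.2-fold), Apol9a (log2 difference -3.33) and Clec1b (8.67-fold). Among lower genes with a bound, Wnt10a was at least 43.1-fold, Cd209f at least 40.8-fold, Ifi202b at least 30.5-fold and Tas2r134 at least 21.9-fold lower. The Klk1b genes and the Apol9 genes are close paralogs, so a probe may carry signal of another member, and their single values are uncertain. The 3 probes of Clec1b ranged from -3.37 to -1.35. Several of these folds rest on a value near background on 1 array, so their size is uncertain. Cox6a2 was at -4.61 in the wild-type library, where the lowest value called above background was -4.79. Rgs9 and Dnah7b were at -4.63 and -4.80 in the library labelled Nr4a-deficient, where it was -5.11. Over the alternative scalings, the log2 difference ranged from 5.81 to 6.88 for Cox6a2 and from -5.96 to -4.50 for Rgs9.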

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

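The control probe ERCC-00012, which belongs to no gene of the mouse, had a median processed signal of 46.2 over 10 spots in the library labelled Nr4a-deficient, above 33.1, the upper limit taken from the 153 negative-control spots of that array. The control probe ERCC-00062 had a median of 36.9 over 10 spots there, above the same limit. In the wild-type library their medians were 42.5 and 19.9, below that array's higher limit of 55.6. Both signals in the library labelled Nr4a-deficient were under 51.1, the lowest signal called well above background on its array. The number of control probes screened is not given here.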

How the results depend on the processing

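No paired analysis was possible because each genotype has 1 library, and no library could be left out. Setting genes to their bounds and leaving out other-cell markers were chosen after the data were seen. The count of genes at least 2-fold higher (1429) stayed within 1.5 times in 9 of 13 alternatives. It was 775 with normexp and quantile normalization, 432 with genes above background on both arrays, 2158 at 1.5-fold and 823 at 4-fold. Of the count lower (1064), 9 of 13 stayed within that range, and it was 1785 without a filter on dim probes, 499 with both arrays above background, 1661 at 1.5-fold and 547 at 4-fold. Without other-cell marker genes the counts were 1379 and 1046. The thresholds and filters change the counts by construction, and the cause of the fall with normexp was not tested.

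The lists' shifts below are medians minus those of matched random lists. Treg signature, Tfh, Th1, effector, naive, proliferation and early T cell receptor genes, and B cell, NK and CD8, and erythroid markers, stayed on their side of the limit in all alternatives run. The 3 other scalings by a single factor shift lists and random lists alike and so check no list's place. The Treg signature, Tfh, proliferation and early T cell receptor lists held no other-cell markers, so leaving those out checked nothing for them. The Treg signature, effector, naive and B cell lists held no gene with a bound, so setting bounds could not move their medians. Places outside the central 95% ended as follows. With the mean in place of the median, they ended for Th17 (0.38), IL-2 and STAT5 (-0.36), chemokine receptors (0.15), myeloid markers (0.13) and granulocyte markers (0.99), and interferon genes reversed (0.022). With cyclic loess they ended for interferon genes (-0.078) and myeloid markers (0.052), with normexp for interferon genes (-0.081), and with the mean of a gene's probes for interferon genes (-0.071) and myeloid markers (0.055). Without a filter on dim probes they ended for Th2 (0.12) and granulocyte markers (0.011). With genes above background on both arrays, they ended for Th2 (0.087), while thymocyte (0.19) and granulocyte markers (-0.081) reversed. Without the most changed member, they ended for Th2 (0.11) and thymocyte markers (-0.067), and with bounds for Th2 (0.14). Lists that newly stood apart were apoptosis with loess (-0.14), normexp (-0.13), the mean of probes (-0.13) and without its most changed member (-0.11), heat shock (-0.27) and pan T cell genes (-0.17) by the mean, and stromal markers without a filter (0.30), with both arrays above background (0.23), by the mean (0.80) and with bounds (0.26). The cause was not tested, except that a list without 1 member, or without genes above background on 1 array, differs by those genes.

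Of 937 values of the 96 named genes under the alternatives, 729 moved by less than the SD of a spot difference, 207 by more, and 1 value of a gene past 2-fold changed sign, Cdkn1a at -1.02 with the mean of its probes. Among genes within 2-fold, Foxp3 (-0.35), Ctla4 (-0.26), Bcl6 (-0.063) and Ifng (-0.27) changed sign with the spike-ins, and Foxp3 also with the median scale, loess and normexp. In at least 1 alternative, 9 genes fell under 2-fold, among them Cxcr5 (0.90), Ly6c1 (0.95), Ly6a (0.97) and Ccr9 (0.87) with the spike-ins, Il5 (0.92), Il17f (0.69) and Cenpf (-0.54) with normexp, and Il18r1 (-0.98) with loess. Signal over background limits dim genes, since the lowest scaled value called above background was -5.11 in the library labelled Nr4a-deficient and -4.79 in the wild-type library.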

Other observations

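A group of genes typical of plasmacytoid dendritic cells was higher in the library labelled Nr4a-deficient, and red cell genes and some macrophage genes were higher in the wild-type library. These genes were chosen after their values were seen, except those named by the rule. Besides Cox6a2, Cd209d, Upb1, Rnase6 and Lifr, the transcription factor genes Bcl11a (9.10-fold), Cbfa2t3 (8.47-fold), Tcf4 (7.57-fold) and Irf8 (3.19-fold) were higher, as were Mzb1 (6.55-fold) and Plac8 (6.21-fold). Smim5 was at least 15.8-fold and Klk1 at least 27.8-fold higher. Siglech, a surface receptor of these cells, had probes that disagreed, with log2 differences of 6.63 and 0.10 at the probes above background on both arrays, the flat probe being the brighter. Its remaining probe was above background only in the library labelled Nr4a-deficient, with a signal of 427 there and 18.5 in the wild-type library. The whole list of 37 such markers, added after the data were seen, had a median of 1.43, with 21 genes at least 2-fold higher and 1 lower; since some were picked for being high, its rank is not given. On the other side, the macrophage genes C1qb (2.74-fold), Adgre1 (2.45-fold) and Cd14 (2.57-fold) were lower, but other myeloid genes such as Mpeg1 (2.63-fold) and Lyz2 (2.04-fold) were higher. Also lower were the haem synthesis gene Alas2 (3.09-fold) and the red cell anion exchanger gene Slc4a1 (3.13-fold).

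All tests on the patterns below were chosen after the results were seen, except those on basophils and on flanking DNA. The limits of the test on Treg cell share were also revised after its values were seen, because the Foxp3 probe lay near background. Under the first limits that explanation would have been excluded, and under the revised ones it stays open.

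Dendritic and B cell markers were higher in the library labelled Nr4a-deficient. Intensity-dependent scaling is argued against, since the B cell list kept 0.953 of its shift after cyclic loess. RNA of plasmacytoid dendritic cells in the sorted cells may account for part of the pattern, because 18 of its markers that no fixed list holds and the rule does not name, listed before their values were looked at, had a median of 0.95, at percentile 100 of matched random lists, although 33 of the 37 listed markers were also above background in the wild-type library and 9 stood in other lists. RNA of B cells stays open, as Ms4a1, Cd79a and Cd79b had a median of 0.818, between the limits set for and against it (1 and 0.5). Pax5, also set for this test, was well above background on neither array. With the spike-ins as the scale the median was 0.45, but that scale lowers every gene by 0.36, so passing the limit there adds no evidence. In the whole B cell list 17 genes lay above 0 and 4 below. Those below were Fcrl1 (-0.55), Vpreb3 (-0.066), Bank1 (-0.058) and Cr2 (-0.024), named after their values were seen. Whether the sort's gate would remove these cells, and whether genotype changed the cells themselves, was not tested.

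Il4, Il13 and Il21 were higher in the library labelled Nr4a-deficient. RNA of basophils or mast cells is argued against, since 0 of Mcpt8, Cpa3, Fcer1a and Ms4a2 were well above background in that library, although Hdc, also expressed by these cells and chosen after its value was seen, was 4.90-fold higher there. Spot noise is argued against for Il4, since its difference was 33.5 times the SD of a single-spot difference of its probe. Il13 and Il21 had 1 spot per array, so the spot noise of their probes was not measured. A larger share of other T cells in that library cannot be told apart from a change in Treg cells. The Treg genes Ctla4, Ikzf2, Tnfrsf18 and Gpr83 had a median of -0.245, short of the limit of -0.5 set for that explanation. The limit against it was a median above -0.25 with at least 2 genes at or above 0, and only Ctla4 (0.11) was. With the spike-ins as the scale the median was -0.61, with none above 0. That scale lowers every gene by 0.36, so passing the limit of -0.5 there adds no evidence. How far a small share of other cells would move these transcripts was not computed. Gpr83 was also not bright, at -2.02 in the library labelled Nr4a-deficient and -1.71 in the wild-type library on the scaled log2 axis. A change of these cytokine genes with genotype remains a hypothesis on 1 library per group.

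The Nr4a1 and Nr4a2 probes were brighter in the library labelled Nr4a-deficient. Scaling of the arrays is argued against, since the lowest log2 difference of these genes over the alternative scalings was 0.496. Swapped labels cannot be told apart from probes outside the deleted parts: all 10 Nr4a3 spots were dimmer in that library (at most 39.7) than in the wild-type library (at least 56.3, against a negative-control limit of 55.6), which a swap would not predict for a probe in a deleted part, but the deleted parts are not in the labels and the scanner software called the probe well above background on neither array. Transcripts made from a targeted allele may also carry the probed sequence, which was not tested.

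Flanking DNA of another mouse strain, carried with targeted alleles, was tested as a source of changed genes near the Nr4a loci. Within 10 Mb of the 3 loci 15 of 340 measured genes (4.41%) were changed at least 2-fold, against 5.75% of all genes with a position, at percentile 19.05 of 2000 random sets of windows, so no excess was found over the 3 loci together. The share was 4.76% of 147 genes near Nr4a1, 7.55% of 53 near Nr4a2 and 2.86% of 140 near Nr4a3. Single loci were not ranked, and strain differences elsewhere in the genome were not tested.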
